A study of Arabidopsis thaliana with 7 samples.

How the data were processed

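Chromatin immunoprecipitation and sequencing (ChIP-seq) was done on 3-day-old etiolated Arabidopsis thaliana seedlings, per the labels' protocols. Seedlings of the MYC2 and MYC3 lines carried the factor with a YPet tag (a yellow fluorescent protein) and spent 2 h in methyl jasmonate gas, 1 µL per L of container. Tissue was fixed in 1% formaldehyde for 20 min, and the tagged factor was recovered with an anti-GFP antibody. The series holds 2 MYC2 libraries, 1 MYC3 library and 4 IgG control libraries from non-transgenic seedlings kept for 2 h in air. Groups and replicate numbers were taken from the sample titles and, for the controls, from the antibody label. The names of the files number the MYC2 libraries 3 and 4 and the MYC3 library 3, where the titles have 1, 2 and 1. Nothing in the labels says whether the MYC2 replicates came from separate cultures, so differences between them can be technical.

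The authors aligned reads with Bowtie2 2.0.5 and called peaks with MACS2 2.0.10 on build TAIR10, per the submitters' processing notes; no role is stated there for each tool. Each ChIP library has its own deposited peak list, so peaks were called per library and not on pooled samples. Peak lists of the IgG controls were not analysed here, and the controls enter only through the values the authors deposited. Each entry holds an interval, a summit, and 4 values. The fold enrichment deposited by the authors is a linear ratio of the ChIP pileup to the local background at the summit. The −log10 p deposited by the authors is that of the peak caller. The score deposited by the authors was the −log10 p times 10, cut to a whole number, and was not used. The deposited −log10 q was -1 in every entry, an unset value, so the planned threshold on q was replaced by a −log10 p of at least 5, as had been fixed for this case. Fold and −log10 p were used only to filter and rank peaks within a list and to describe them.

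Many intervals hold several summits. As fixed beforehand, the main lists keep the summit of highest −log10 p in each interval on chromosomes 1 to 5, then the 5000 peaks of highest −log10 p. MYC2 replicate 2 has only 4623 such peaks, all of which were kept. An alternative chosen after seeing the data keeps every summit as its own peak.

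Read totals were not used here. The fold and p of an entry fix its pileup and its background when p is the Poisson chance of a larger pileup. Solved in this way, the pileup came out whole, within 0.05, in 100% of 74490, 66043 and 73854 entries of MYC2 replicate 1, MYC2 replicate 2 and MYC3. The lowest recovered background, 43.27, 30.02 and 19.53 fragments per position, was read as the depth of each library. It depends on fragment length as well as on the number of reads.

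Gene names, positions and the protein-coding class came from a gene table of assembly TAIR10.1, with no strand and no exons. Because the files use TAIR10, summits were checked against the table in 26 segments of 5 Mb: shifting the table by up to 20000 bp either way in steps of 100 bp, most summits lay outside genes at a shift of 0 in 23 segments and at 100 bp in the rest. No genome sequence was used here, so the planned search for the G-box was not run. With no strand, the planned window around the gene start was applied at both annotated gene ends, from 1500 bp outside the gene to 500 bp inside it. A gene with a summit in either window counts as a target. Folds printed for a gene are those of its best-ranked summit in each library, which can be different sites, also at opposite gene ends. A summit can count for several genes, and it was not told apart whether it lies before or behind a gene. Exonic, intronic and UTR positions were not analysed here. In place of the promoter share, the share of summits outside every annotated gene and within 1000 bp of a protein-coding gene end was compared with 100000 uniform random positions by Fisher's exact test, two-sided.

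Peaks of 2 lists were called shared when their summits lay within 100 bp. Each shared percentage was set against 100 circular shifts of the second list within each chromosome, one-sided, with a smallest possible p of 0.0099; the alternatives by overlap of intervals had 20 shifts and a smallest possible p of 0.0476. Percentages carry 95% Wilson intervals, which cover counting error only. Neither the circular shifts nor the counts expected of independent gene lists keep the preference of summits for places beside genes. Both expectations can therefore be too low, and part of an excess over them can come from that preference. A target gene of both MYC2 lists is called a MYC2 consensus target. Gene lists were tested by Fisher's exact test, two-sided, over 27444 protein-coding genes, with Benjamini-Hochberg adjustment over 64 tests: 16 lists in each of MYC2 replicate 1, MYC2 replicate 2, MYC3 and the MYC2 consensus. The lists, the tests and the rule for named genes were fixed before the data were examined. The lists hold 230 genes, all of them in the gene table. Named are up to 4 consensus targets of best mean MYC2 rank per list, up to 2 genes without a summit for each jasmonate list, the 10 best consensus peaks, the 10 best MYC3 peaks, and 5 peaks in each direction that lack an entry of the other factor. MYC2 and MYC3 themselves were always named, and other genes named were chosen after their values were seen. No planned test compares MYC2 with MYC3, since MYC3 has 1 library; a comparison of ranks by gene list was added. Both factors were set against IgG controls, and part of any overlap can come from shared controls. The controls also differ from every ChIP library in antibody, in line and in treatment (air in place of methyl jasmonate). Signal that comes from these differences would count as enrichment for both factors, in the overlaps and in the gene lists. Neither was tested.

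The peak names in the files carry the same run tag in MYC2 replicate 1 and MYC3, and another in MYC2 replicate 2. Factor and batch are therefore partly confounded. Shared peaks, target counts and fold correlations are given for both MYC2 libraries. Gene lists are compared mainly with the MYC2 consensus, and ranks by gene list with the mean of both libraries.

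The functions were tested on simulated data. For the MYC2 replicate overlap, a planted share of 59.5% of 5000 peaks came back as 59.7%, and 6% of 100 pairs of unrelated lists passed the threshold. A separate unrelated pair, drawn once, shared 1.1% with a p of 0.0297. For the gene lists over 27444 genes, 93.8% of lists given targets at 70% were called, and 0% of lists without planted targets. Targets were planted only in the JAZ, biosynthesis, glucosinolate and abscisic acid lists, of 13 to 22 genes. The adjustment there was over 16 lists and not over 64 tests. Shorter lists and weaker effects were not simulated. Of 19718 simulated pileups, 100% were recovered within 0.05. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.

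Alternatives changed 1 choice at a time: list length (1000 or 10000 peaks), threshold, fold of at least 3, ranking by fold, distance between summits (50 bp), overlap of intervals, window (500 bp outside to 100 bp inside, or 3000 to 500 bp), a 500 bp promoter, and leaving out each MYC2 replicate. Those added after seeing the data were every summit kept, a −log10 p of at least 10, each summit assigned to its nearest gene only, and the MYC3 list without a segment next to the MYC3 gene.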

Results

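The 2 MYC2 libraries and the MYC3 library show where these bHLH transcription factors of jasmonate signalling sat on the genome of etiolated seedlings after 2 h in methyl jasmonate, the volatile form of the hormone. Among the strongest sites of both factors were those of jasmonate pathway genes. They included MYC2 itself, the biosynthesis genes OPR3 and OPCL1, and JAZ6, JAZ9 and JAZ10, whose products repress the pathway. With 2 libraries of MYC2 and 1 of MYC3, values are given per library and no SD is given.

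The deposited lists hold 279760, 338462 and 331134 entries for MYC2 replicate 1, MYC2 replicate 2 and MYC3, most of them below the threshold. On chromosomes 1 to 5, 32894, 12395 and 22563 entries reached it. On chromosomes 1 to 5, intervals with a −log10 p of at least 5 numbered 9453, 4623 and 7510. The main lists of 5000, 4623 and 5000 peaks reached down to a −log10 p of 18.4, 5.002 and 9.38. Their median fold enrichment, as deposited by the authors, was 3.74, 2.48 and 3.70, and the highest fold was 10.2, 11.3 and 15.8. The median pileup behind a peak was 178, 82 and 81 fragments over a background of 43.27, 30.02 and 19.53, so folds rest on the most fragments in MYC2 replicate 1. The highest fold belonged to the MYC2 gene in both MYC2 libraries and to JAZ9 in the MYC3 library.

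Binding lay mostly beside genes. Outside genes and within 1000 bp of a protein-coding gene end lay 56.1% of the MYC2 replicate 1 summits (95% Wilson interval 54.7 to 57.4). The share was 55.0% (53.5 to 56.4) in MYC2 replicate 2 and 53.8% (52.4 to 55.2) in MYC3. Of random positions 19.2% fell in this class, and the odds ratios were 5.36, 5.13 and 4.89 (Fisher's exact test, p at the lower limit written, 1e-300, in each library). Inside protein-coding genes the shares were 25.8%, 23.1% and 27.1%, against 54.2% of random positions. Summits farther from genes took 15.7% (p = 0.0978), 19.6% (p = 1.63e-07) and 16.4% (p = 0.726) by the same exact test, against 16.6% of random positions.

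The first question of the design is which genes MYC2 binds. The best-ranked peak of both MYC2 libraries stood next to the MYC2 gene itself (AT1G32640), on chromosome 1 in the interval 11794036 to 11803706 of TAIR10. Its summit at 11801741 had a fold of 10.2 in replicate 1 and 11.3 in replicate 2. ERF13 (AT2G44840), a gene of the ethylene response factor family, came next, at 18494314 on chromosome 2 (10.1 and 9.71). It was followed by a further interval near MYC2, 11806535 to 11807821, between MYC2 and AT1G32650 (10.1 and 9.03), and by AT2G22760 at 9677610 on chromosome 2 (10.1 and 9.93). The 10 kb window from 11800000 holds both sites near MYC2. Its lower quartile of fold over all entries was raised in MYC2 replicate 1, MYC2 replicate 2 and MYC3 (4.00, 1.89 and 1.61). Whether extra copies of the locus in the tagged line add to the folds of these sites was not tested. GRX480, which codes for a glutaredoxin, had its summit at 10014293 on chromosome 1 with folds of 9.40 and 10.2. MSRB7, a methionine sulfoxide reductase gene, AT1G20310, TAT3, a tyrosine aminotransferase gene, JAZ1 and JAZ10 completed the 10 best peaks, with folds from 8.92 to 9.87 in both libraries. The JAZ10 summit, at 4218807 on chromosome 5, lay inside the annotated gene, and those of the other 9 outside protein-coding genes. In all, 4818 genes (17.6% of 27444) were targets in both MYC2 libraries, out of 6618 in replicate 1 and 5873 in replicate 2. Independent lists of that length would share 1416, with all genes taken as alike. The count depended on the window and the gene assignment: 2328 genes with the window of 500 bp outside to 100 bp inside, 7586 with 3000 bp, and 3109 when each summit went to its nearest gene only.

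JAZ genes, which code for repressors of MYC factors, were MYC2 targets in 11 of 13 cases, against 17.5% of other genes (odds ratio 25.9, Fisher's exact test, adjusted p = 8.51e-06). JAZ10 had folds of 9.82 and 9.001 in the 2 replicates, JAZ1 9.20 and 9.13, JAZ9 9.71 and 8.35, and JAZ6 9.22 and 7.60. JAZ2 was in the replicate 2 list only, because the best summit of its interval lay elsewhere in the other libraries; with every summit kept, it had 8.98 and 9.21. JAZ11 had no summit in any main list. Genes of jasmonate biosynthesis were targets in 11 of 17 cases (odds ratio 8.63, adjusted exact p = 0.000224). AOS (AT5G42650), allene oxide synthase, had folds of 9.41 and 8.47. OPR3 (AT2G06050), the reductase of 12-oxo-phytodienoic acid, had 8.93 and 7.59, and OPCL1, a CoA ligase of the pathway, had 8.48 and 7.82. AOC1, an allene oxide cyclase gene, had 6.88 and 5.55; its neighbours AOC2 and AOC3 shared 1 summit with each other. KAT2 and LOX4 had no summit in the main lists; LOX4 had summits of 4.91 and 3.61 in intervals led by another summit. Both list calls held in all 9 alternatives that change the MYC2 lists.

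Genes that break down or inactivate jasmonates were targets in 4 of 10 cases, which did not pass the test (adjusted exact p = 0.134). IAR3, an amidohydrolase gene, stood out with folds of 9.53 and 9.28, followed by CYP94B1 (7.64 and 6.10), CYP94B3 (4.83 and 3.33) and the sulfotransferase gene ST2A (3.90 and 3.31). The CYP94B1 folds belong to different sites, at 25408797 in replicate 1 and 25412154 in replicate 2. ILL6 and CYP94C1 were absent from the main lists because the best summit of their interval lay elsewhere. Among all summits past the threshold, ILL6 had folds of 6.48 and 4.83 and CYP94C1 2.71 and 1.84. The list reached 6 of 10 members with the nearest gene only (adjusted exact p = 0.000942) and with every summit kept as a peak (0.00306); in the latter the housekeeping control list, at 5 of 12, also passed (0.0342).

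Among the receptor, co-repressor and MYC-clade bHLH genes, 5 of 12 were MYC2 targets (adjusted exact p = 0.0836). The list passed in 4 of 9 alternatives, among them the 1000 best peaks (adjusted exact p = 0.00351). By mean rank, MYC2 was followed by JAM1, with folds of 10.03 and 8.93, and by the adaptor gene NINJA, with 8.51 and 7.69. JAM2 came next with 8.87 and 7.58. JAM1 and JAM2 code for bHLH repressors of jasmonate responses. MYC3 (AT5G46760) was in the replicate 1 list at rank 1200 with a fold of 5.0 and not in the replicate 2 list. MYC4, bHLH14 and JAM3 had no summit in any main list, although MYC4 had summits of 5.04 and 2.35 in intervals led by another. Transcription factor genes linked to jasmonate were targets in 9 of 16 cases (odds ratio 6.05, adjusted exact p = 0.00205). They included WRKY40 (8.72 and 7.70), WRKY18 (8.38 and 7.55), ANAC055 (7.88 and 7.85) and ANAC019 (8.04 and 6.45), and also the ethylene and jasmonate response gene ERF1 (5.85 and 5.51), while MYB21 and WRKY70 had no summit in the main lists. The call was lost with the window of 500 bp to 100 bp (adjusted exact p = 0.120).

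Defence outputs of jasmonate were targets in 6 of 15 cases (adjusted exact p = 0.0671), and passed only with the nearest gene (0.00937) among 9 alternatives. TAT3 had folds of 8.92 and 9.25, the terpene synthase gene TPS10 5.39 and 3.64, and the vegetative storage protein genes VSP2 4.56 and 2.998 and VSP1 3.86 and 2.15. THI2.1 and PDF1.2b had no summit at the threshold even with every summit kept. Glucosinolate genes, which make sulfur-rich defence compounds, were targets in 9 of 22 cases (odds ratio 3.26, adjusted exact p = 0.0252). In MYC2 replicate 1 alone, 10 of 22 did not pass (adjusted exact p = 0.0509). GGP1 had 8.20 and 7.28, the cytochrome P450 gene CYP79B3 7.88 and 5.67, SUR1 6.82 and 4.19, and the glucosyltransferase gene UGT74B1 6.37 and 4.32. Of the MYB regulators of this pathway, MYB28 (3.30 and 2.58) was a target and MYB29, MYB34, MYB51, MYB76 and MYB122 were outside the main lists. MYB34 had summits of 3.75 and 2.63 in intervals led by another.

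Genes of other hormones and of light signalling were also among the MYC2 targets. All 5 DELLA genes, repressors of gibberellin responses, were consensus targets (adjusted exact p = 0.00133), led by RGL3 with folds of 7.87 and 5.58 and RGA with 5.63 and 3.801. RGL1 had 5.58 and 3.32, and GAI 4.16 and 3.09. With the window of 500 bp to 100 bp none of the 5 remained (0%). Abscisic acid genes were targets in 10 of 18 cases (odds ratio 5.88, adjusted exact p = 0.00177), among them the phosphatase genes HAB1 (6.49 and 4.39) and ABI1 (5.603 and 4.65), the receptor gene PYL4 (6.39 and 5.24), and ABF3 (6.31 and 3.54). That call was lost with the 1000 best peaks (adjusted exact p = 0.0708) and with the narrow window (0.0626). Ethylene genes numbered 7 of 17 (odds ratio 3.29, adjusted exact p = 0.0399), with EBF1 at 7.05 and 6.36, the receptor gene ERS1 at 7.51 and 5.32, EIL1 at 6.05 and 4.35 and EBF2 at 4.22 and 3.47. Light signalling genes also numbered 7 of 17 (adjusted exact p = 0.0399), with SPA1 at 8.57 and 6.18, PIF5 at 5.85 and 3.45, HFR1 at 5.26 and 3.90 and PHYB at 4.73 and 2.98. The PHYB folds belong to different sites, at 8139651 in replicate 1 and 8138514 in replicate 2. The ethylene call was lost in 5 of 9 alternatives, 1 of them leaving out MYC2 replicate 1 (adjusted exact p = 0.126), and the light call in 4.

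The remaining lists did not pass. Salicylic acid genes were targets in 4 of 10 cases (adjusted exact p = 0.134; 0.0188 with the 3000 bp window and 0.0370 with the nearest gene only), with EDS5 at folds of 6.66 and 4.74, PAD4 at 3.77 and 2.29, ICS1 at 3.18 and 1.81, and CBP60G at 2.69 and 2.03. Flavonoid and anthocyanin genes gave 4 of 15 (adjusted exact p = 0.383), with MYB113 at 6.20 and 3.803, and CHS, F3H and DFR below 4 in both libraries. Auxin genes gave 3 of 15 (adjusted exact p = 0.813): IAA5 (6.18 and 3.56), ASA1 (4.28 and 3.17) and YUC9 (5.36 and 2.59). The photosynthesis control list gave 2 of 16 genes, LHCA1 and RBCS3B (adjusted exact p = 1.00). The housekeeping control list gave 4 of 12 genes (adjusted exact p = 0.318). Of these, TUB2 had folds of 8.83 and 6.45, and ACT2, TIP41 and UBQ10 had 4.10, 4.53 and 4.18 in replicate 1. The housekeeping share was still above that of other genes, at 33.3% against 17.5% (odds ratio 2.35). For MYC3 it was 41.7% against 24.2%. With only 12 genes, this list is therefore not a clean negative control. It passed for the MYC2 consensus with every summit kept (adjusted exact p = 0.0342).

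**Figure D1:**
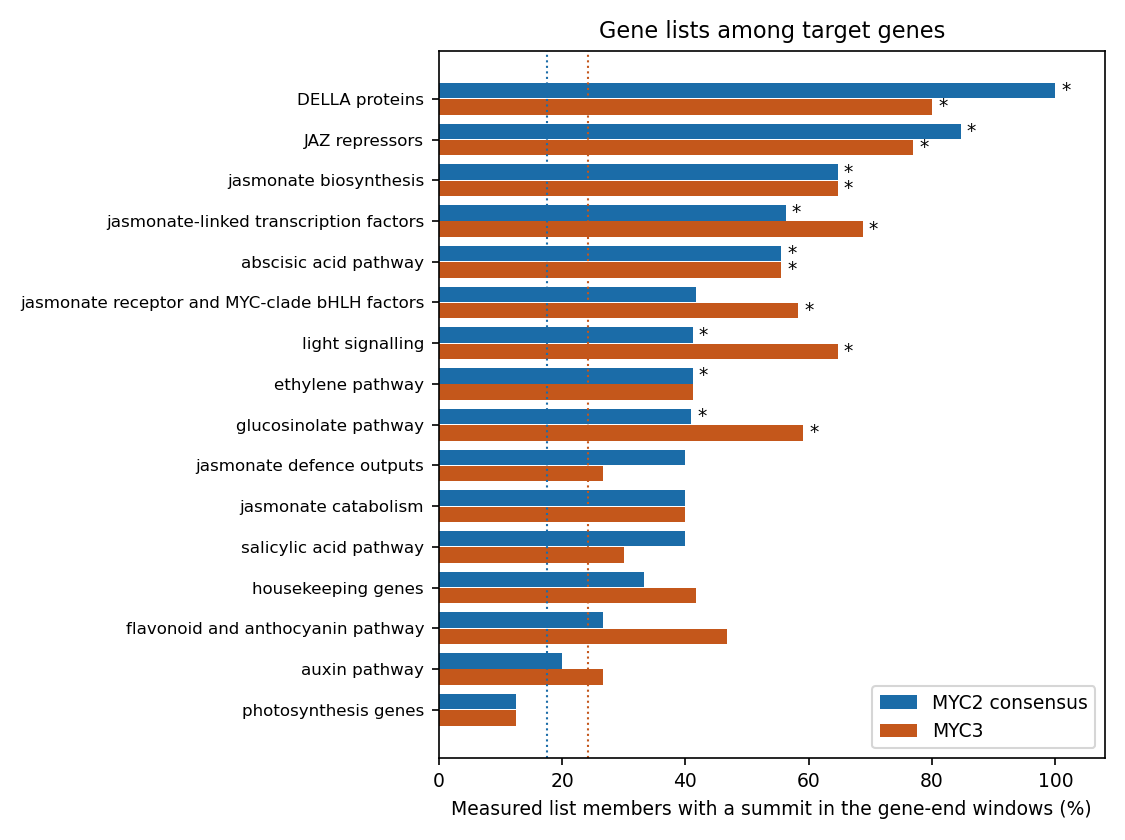
Share of the measured members of each gene list (%) with a summit in the gene-end windows, for the MYC2 consensus (blue) and MYC3 (orange). Asterisks mark lists with a higher share than other genes by Fisher's exact test after adjustment, and dotted lines the share of other genes, 17.5% for MYC2 and 24.2% for MYC3; JAZ repressors stand at 84.6% and 76.9%, photosynthesis genes at 12.5% in both.

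The MYC2 replicates shared the strong sites and parted at the weak ones. The MYC2, ERF13, AT2G22760 and GRX480 sites were within the 10 best ranks of both libraries. Of the 5000 peaks of replicate 1, 3209 (64.2%, 62.8 to 65.5) had a replicate 2 summit within 100 bp, against a mean of 0.765% under circular shifts (permutation p = 0.0099, the smallest the shifts allow). The share was 92.2% for the 1000 best peaks and 31% for ranks 4001 to 5000. Of the replicate 2 peaks, 69.4% (68.1 to 70.7) were shared with replicate 1. Taking all peaks past the threshold lowered the share of replicate 1 to 36.8%, as its list then held 9453 peaks and that of replicate 2 4623.

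**Figure D2:**
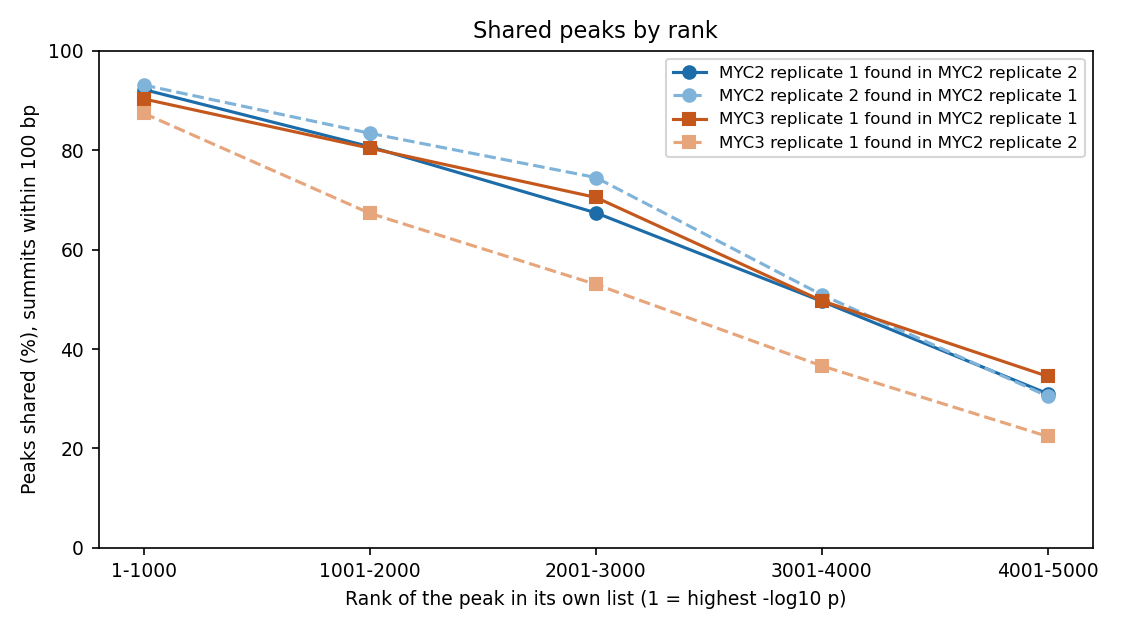
Percentage of peaks shared, with summits within 100 bp, against the rank class of the peak in its own list, for both directions between the MYC2 replicates and for MYC3 in each of them. All 4 lines fall with rank, from between 87.4% and 93.1% in the best 1000 to between 22.4% and 34.5% in the last class.

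The second question is how far MYC3 binds the same places. MYC3 shared its leading sites with MYC2. Its best peak lay beside ACT1 on chromosome 2 (interval 15770391 to 15780610, summit 15778848, fold 15.8), a site of folds 8.16 and 6.63 in the MYC2 libraries. JAZ9 (15.8), AT3G60750 (14.4), AT2G22760 (15.7) and the site between AT4G34400 and RRTF1 (14.3) followed. ORA47 (14.9), an AP2/ERF gene of jasmonate biosynthesis control, AT3G59340 (13.8), AT2G32150 (14.3), ERF13 (15.3) and IAR3 (15.2) completed the 10 best. All 10 were in the list of MYC2 replicate 1 and 9 in that of replicate 2. ORA47 was missing there because another summit led its interval; its own had a fold of 8.66. The MYC2 gene had a MYC3 fold of 12.2, at rank 82.

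Of the 5000 MYC3 peaks, 65.1% (63.7 to 66.4) had a summit of MYC2 replicate 1 within 100 bp and 53.3% (52.0 to 54.7) one of replicate 2. Circular shifts gave 0.835% and 0.774% (permutation p = 0.0099, the smallest possible, for both). The first value is within the run tag shared by those libraries and the second across tags. How these compare with the share between the MYC2 replicates, also across tags, turned with the setting. That share was above both with the 1000 best peaks of each library (79.6% against 64.8% and 60.8%). With every summit kept, at 5000 peaks per library, it was also above both (72.6% against 70.2% and 61.8%). It was below both with all peaks past the threshold (36.8% against 63.9% and 38.8%). Those lists differ in length: 9453 peaks of replicate 1 were sought among 4623 of replicate 2. Such a difference in length lowers a share by itself, so that setting does not compare the pairs on equal terms. A total of 2394 sites were in all 3 lists. Across these sites, which are not independent replicates, the Spearman correlation of fold was 0.908 between the MYC2 replicates, 0.757 between MYC2 replicate 1 and MYC3, and 0.710 between MYC2 replicate 2 and MYC3.

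Of the 4818 MYC2 consensus target genes, 4045 (84.0%) were also MYC3 targets, where independent lists would share 1167 with all genes taken as alike. AOS, OPR3 and OPCL1 were among them, with MYC3 folds of 9.69, 11.7 and 13.9, as were JAZ6 (14.1), JAZ10 (13.6), JAM1 (13.8), JAM2 (12.6), NINJA (10.7), ANAC055 (12.9) and RGL3 (12.05). The other 773 consensus targets were outside the MYC3 list. Some such cases were set by the rule of 1 summit per interval: JAZ1, IAA5, RGL1 and TPS10 had MYC3 summits past the threshold, with folds of 12.2, 4.87, 4.08 and 3.804, in intervals led by another summit. ICS1 had none. With every summit kept, 576 of 3848 consensus targets were outside the MYC3 list. Conversely, 1166 of the 6646 MYC3 targets were in neither MYC2 list. Against MYC2 replicate 1 alone, 1469 targets were outside the MYC3 list and 1497 MYC3 targets outside MYC2, and against replicate 2 alone these counts were 1497 and 2270. Of the targets of replicate 1, 77.8% were also MYC3 targets, and of those of replicate 2 74.5%, both below the 84.0% of the consensus. Between the MYC2 replicates, 72.8% of the replicate 1 targets and 82.0% of the replicate 2 targets were shared.

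MYC3 targets were enriched in 8 lists, 7 of them also enriched for the MYC2 consensus. JAZ genes were MYC3 targets in 10 of 13 cases (odds ratio 10.4, Fisher's exact test, adjusted p = 0.000858), and biosynthesis genes in 11 of 17 (5.75, 0.00198). Jasmonate-linked transcription factors reached 11 of 16 (6.89, 0.00134), with WRKY40 at a fold of 11.05 and ANAC019 at 11.95. Glucosinolate genes reached 13 of 22 (4.53, 0.00200), with CYP79B3 at 11.9, SUR1 at 10.1 and UGT74B1 at 9.54. Light signalling genes reached 11 of 17 (5.75, 0.00198), with SPA1 at 12.96 and PHYB at 5.95. Abscisic acid genes reached 10 of 18 (3.92, 0.0129) and DELLA genes 4 of 5 (12.5, 0.0328). The receptor and bHLH list reached 7 of 12 (4.38, 0.0293), a call that was lost in 4 of the 8 alternatives that change the MYC3 list, among them leaving out the segment around the MYC3 gene (adjusted exact p = 0.0884). In MYC2 replicate 1 alone this list also gave 7 of 12 (adjusted exact p = 0.0293). Ethylene genes reached 7 of 17 (adjusted exact p = 0.229), jasmonate catabolism 4 of 10 (0.337), flavonoid genes 7 of 15 (0.117), defence outputs and auxin genes 4 of 15 each (0.814), salicylic acid genes 3 of 10 (0.800), housekeeping genes 5 of 12 (0.258) and photosynthesis genes 2 of 16 (0.450). Jasmonate catabolism passed in 3 of 8 alternatives (adjusted exact p from 0.000688) and flavonoid genes in 1 (0.0390). Differences between the factors in these counts were not tested. The share of other genes was 17.5% for the MYC2 consensus and 24.2% for MYC3, so an equal count can pass for 1 and not for the other. Ethylene genes gave 7 of 17 in MYC2 replicate 2 alone as well (adjusted exact p = 0.119). The narrow window ended the MYC3 calls for biosynthesis (adjusted exact p = 0.0652), jasmonate-linked factors (0.257), the receptor list (0.342), abscisic acid (0.417) and DELLA genes (1.00). Light signalling was lost with the nearest gene only (0.0624), abscisic acid also with the 1000 (0.114) and 10000 best peaks (0.0695), and DELLA genes also with these (0.339 and 0.109), the 3000 bp window (0.119) and ranking by fold (0.154).

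Few sites of either factor lacked any entry of the other. Of 3209 MYC2 consensus peaks, 114 (3.55%) had no MYC3 entry of any strength within 100 bp. The best-ranked of these lay beside AT1G75230 (chromosome 1, summit 28233964, folds 7.83 and 6.08), AT4G23510 (6.13 and 4.92), AT3G05900 (6.50 and 4.18), JAL34 (5.94 and 4.57) and within AT3G11420 (6.94 and 4.00). Of the 5000 MYC3 peaks, 113 (2.26%) had no entry of either MYC2 library. These were led by AT3G54460 (chromosome 3, summit 20167601, fold 7.0), RALFL33 (7.41), AT2G03240 (7.06), PUB22, a ubiquitin ligase gene (5.94), and HSFA2, a heat shock factor gene (5.75). The distances of these 10 sites to the nearest entry of the other factor ran from 103 to 266 bp. Entries below the threshold are dense in all lists, so an entry within 100 bp is no sign of binding. Against single libraries the shares were higher: 6.06% of MYC3 peaks had no entry of MYC2 replicate 1 and 11.4% none of replicate 2, and 5.2% and 8.07% of the peaks of these replicates had no MYC3 entry. Between the MYC2 replicates the shares were 8.68% of replicate 1 and 7.42% of replicate 2, in the same range.

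The MYC3 gene lay in a segment of raised fold in the MYC3 library. From 18920000 to 18989999 on chromosome 5, the lower quartile of fold over all entries was between 1.34 and 2.1 in each of 7 adjacent windows of 10 kb. In the 24 windows around them it was between 0.711 and 1.20. The segment held 141 summits at the threshold and 4 peaks of the main list. The MYC3 gene's own peak, with a fold of 10.2 at rank 146, was read against this raised level.

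**Figure D3:**
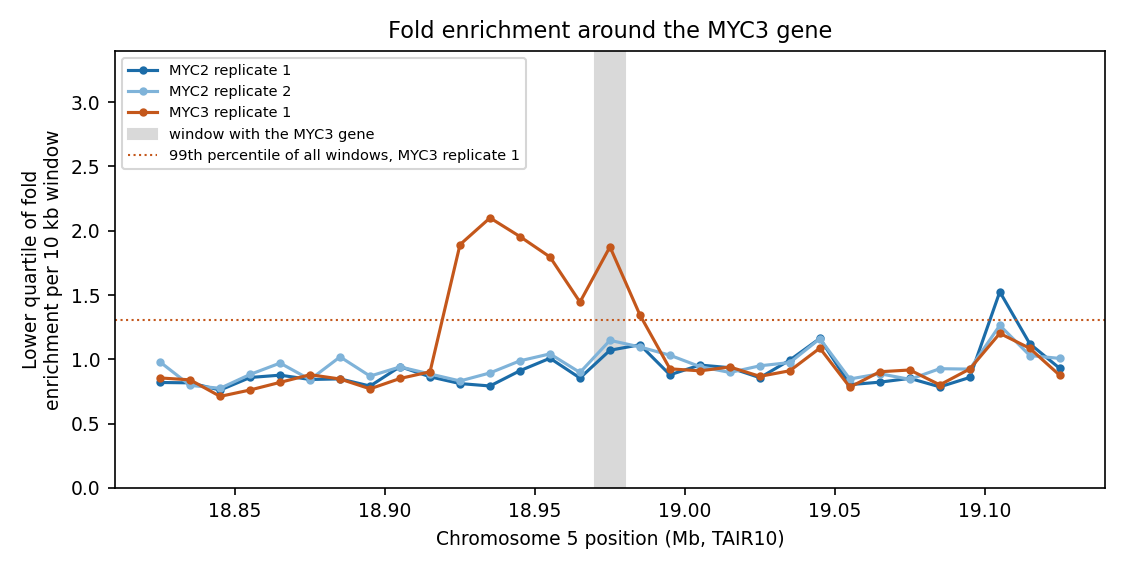
Lower quartile of the deposited fold enrichment over all entries in each 10 kb window, against position on chromosome 5 (TAIR10, Mb), in the 3 libraries; the grey band is the window that holds the MYC3 gene and the dotted line the 99th percentile of all windows of the MYC3 library (1.302). The MYC3 library lies between 1.34 and 2.1 over 7 windows, where neither MYC2 library passes its own 99th percentile.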

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

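Chloroplast DNA, which holds no place in the comparisons of nuclear genes, had entries past the threshold in 2 of the 3 libraries, and this was looked at only after the data were seen. In the MYC3 library 299 of 304 chloroplast entries (98.4%) had a −log10 p of at least 5, with a median fold of 1.76 and a highest fold of 1.93. In MYC2 replicate 2 it was 20 of 132 entries (15.2%), with a highest fold of 1.34. In MYC2 replicate 1 it was 0 of 112, with a highest fold of 1.15. Mitochondrial DNA had 1 entry past the threshold in MYC3, 1 in MYC2 replicate 2 and 0 in MYC2 replicate 1. The IgG controls have no peak list in use here, and no explanation was tested.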

How the results depend on the processing

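The alternatives fixed before the data were examined and those added after (every summit kept, a −log10 p of at least 10, the nearest gene only, and leaving out the segment around the MYC3 gene) changed 1 choice at a time. Planned thresholds on q and every alternative for the G-box were not run, for lack of q-values and of a genome sequence; the planned list of all peaks past a q was run with −log10 p of at least 5. No paired analysis was possible because MYC3 has 1 library. The overlap of the MYC2 replicates (35.6% to 87.9%), that of MYC3 with MYC2 (mean of both libraries, 50.3% to 85.0%) and the share of summits beside genes (39.9% to 57.8%) kept their side of the threshold in every alternative run. The upper ends of both overlaps are from intervals sharing 1 bp, where circular shifts alone gave 43.7% to 47.7%. The 10000 best peaks and all peaks past the threshold are the same lists, as no library has 10000. Counts followed the construction of the lists. Peaks in MYC2 replicate 1, MYC2 replicate 2 and MYC3 numbered 3748, 1530 and 3697 with a fold of at least 3, and 32894, 12395 and 22563 with every summit kept; a −log10 p of at least 10 left 2864 in MYC2 replicate 2 and 4787 in MYC3. With the 1000 best peaks there were 1068 MYC2 consensus targets, 779 shared with MYC3, 289 outside it, and 406 MYC3 targets outside MYC2. The window of 500 bp to 100 bp gave 2328, 1868 and 460 for the same MYC2 counts and 3 enriched lists for each factor; the 3000 bp window gave 7586 consensus and 6579 shared targets, and the nearest gene only 3109 and 2495. With the 10000 best peaks 5 lists were enriched for MYC3, against 8. Leaving out a MYC2 replicate gave 1469 to 1497 MYC2 targets outside the MYC3 list and 1497 to 2270 MYC3 targets outside MYC2, since 1 MYC2 list then defines the targets in place of both, or of either. DELLA genes reversed with the narrow window, to 0% for both factors, which leaves out their summits. Calls for JAZ genes (adjusted p up to 0.000499 for MYC2 and 0.0114 for MYC3) and glucosinolate genes (up to 0.0493 and 0.0271) held in all alternatives that change the list tested, 9 for MYC2 and 8 for MYC3. Over these alternatives, 230 calls for single lists were as before, 26 were lost and 14 gained, and the cause was not tested. The glucosinolate call of MYC2 lay near the threshold. In MYC2 replicate 1 alone, 10 of 22 of these genes were targets, with an adjusted exact p of 0.0509 in the main tests. Leaving out replicate 2 enters that same list more than once in the adjustment, so its pass there is no separate support.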

Other observations

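The tests on the MYC3 segment as extra copies and on its background, the test on the run tag, the symbol families other than transcription factors, the comparison with the MYC2 locus, and an exclusion within the families were chosen only after the results were seen. Transcription factor genes outside the 16 fixed lists were grouped by symbol or synonym and compared with 10155 named genes outside the lists. Of 69 WRKY genes, 31 (44.9%) were MYC3 targets, against 27.9% of other named genes (Fisher's exact test, adjusted p = 0.0389 over 14 tests), where genes with the same space to their neighbours would give 20.2. MYC2 consensus targets held 22 of the 69 (31.9%), against 20.0% (adjusted exact p = 0.0770). WRKY17 had folds of 9.26, 8.19 and 9.01 in MYC2 replicate 1, MYC2 replicate 2 and MYC3, and WRKY75 had 7.41, 4.23 and 10.1. The difference between the factors was not tested.

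Among MYC2 consensus targets were 7 of 14 GRAS genes, led by SCL13 with folds of 6.24 and 5.89, and 3 of 4 ZAT genes (adjusted exact p = 0.0770 for both). AP2/ERF genes gave 17 of 53 (0.0883), with ERF-1 at 9.53 and 9.32 and ERF2 at 7.66 and 6.88, NAC genes 20 of 96 (0.819), MYB genes 20 of 118 (0.621) and bHLH genes 1 of 19 (0.234). The hypothesis that MYC2 consensus targets are enriched in such families was not borne out at the threshold, 0.0770 being the smallest adjusted p. Symbols shared with other proteins, such as translation release factors named ERF, had at first been counted; before they were excluded, the smallest adjusted p was 0.156, and the WRKY value of MYC3 was the same 0.0389. Among other symbol families, UGT genes, which code for glycosyltransferases, came nearest to the threshold, with 23 of 57 as MYC2 consensus targets (40.4% against 20.0%, adjusted exact p = 0.0686 over 174 tests).

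Whether MYC3 and MYC2 rank some pathways differently was tested on 4045 genes with a summit in all 3 lists, each library ranked anew over these genes. The 9 glucosinolate genes had a median rank difference of -503.5 places (MYC3 minus the mean of MYC2), at percentile 0.71 (of 100) among 10000 random lists of like rank. After adjustment over the lists tested, the share of random lists as far out was 0.202, and no list passed; between the MYC2 replicates the same 9 genes differed by 18 places. These are descriptions of 3 libraries and not tests of the factors.

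For the raised segment at the MYC3 gene, low coverage of IgG controls shared by all libraries is argued against by the MYC2 libraries, whose higher median fold in the segment was 1.15, below the 99th percentile of windows in both (1.70 and 1.45). Against low coverage of a control used for MYC3 alone stands the recovered background of the segment, with a median of 22.3 over 210 entries, against a median of 21.01 over runs of as many windows and a lowest value of 19.53. Dense MYC3 binding stays open. Of the 7 windows, 1 passed the 99th percentile of windows with as many summits at the threshold. But 3 of the 7 hold more such summits than any other window of that library, which leaves them no match. The windows from 18950000 and 18980000 had only 3 and 10 matches. Those from 18930000 and 18960000, with 80 and 32 matches, lay at percentiles 100 and 71.9. A raised fold itself adds summits at the threshold, so this match cannot tell dense binding from extra copies. Extra copies of the MYC3 locus in the tagged line remain a candidate explanation, as 7 adjacent windows were raised in the MYC3 library and 0 of them in either MYC2 library; this is a hypothesis found and tested on the same data. Around the MYC2 gene there was no run of 3 such windows in either MYC2 library, but the windows from 11800000 and 11820000 were raised in both, the second (2.37 and 1.75) not in MYC3 (1.15).

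MYC2 replicate 1 had 2.04 times as many peaks past the threshold as replicate 2. Thinned to 69.4% of its fragments, the background of replicate 2, replicate 1 kept 8453 ± 17.8 peaks (SD over 20 draws), 1.83 times those of replicate 2. A difference in depth, as read from the background, thus accounts for little of the gap. A weaker enrichment in replicate 2 and its other run tag were not tested for this count and stay open, and the design gives no biological difference between replicates to test.

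The MYC3 list shared 65.1% with MYC2 replicate 1 and 53.3% with replicate 2. Replicate 1 cut to the list length of replicate 2 shared 62.2%, and thinned to 15.4% of its fragments, which left about as many peaks (4610 on average), 55.2% ± 0.511 (SD over 20 draws). Such thinning lowers depth, far below that of replicate 2, and leaves enrichment as it was, so it does not test a weaker signal of replicate 2, which stays open. The run tag stays open as well: the fold correlation of MYC2 replicate 1 with MYC3, 0.757, was below the 0.908 between the MYC2 replicates across tags but above the 0.710 of replicate 2 with MYC3. This decides nothing, since libraries of 1 factor can correlate more than libraries of 1 tag for reasons other than the tag.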
